A study of Homo sapiens with 4 samples.

How the data were processed

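Gene expression was measured in viable basal keratinocytes sorted for alpha 6 integrin from human foot skin, with 2 arrays of the sole and 2 arrays of the back of the foot. Per the labels' protocols, punch biopsies were treated with dispase, the epidermis was trypsinized, and RNA was amplified in a single round with random primers before hybridisation to Affymetrix exon arrays. The design text of the series states distinct donors, but it does not say whether a replicate number marks a donor, so the p-values measure the spread between these arrays.

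The deposited values are on a log2 scale, summarized per transcript cluster, with a separate column for each array. Affymetrix Expression Console, PLIER (a probe-level summary method) and the build hg19 are named per the submitters' processing notes. Versions, background correction and between-array normalization are not given in the sources used here. The log base was inferred from the values: the largest, 13.55, exceeds the natural log of the largest 16-bit scanner value, 11.09. A probe-level summary can compress differences of dim transcripts, and the arrays' quantiles were close but not identical. Medians over all 147768 rows were 3.37 and 3.31 for the back-of-foot arrays and 3.34 and 3.37 for the sole arrays.

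Rows were named through the platform's gene table, with symbols updated through gene identifiers. Of the rows, 21623 named 1 gene, 4333 named several and 121812 were not listed there, which leaves them unnamed here. The updated symbols of 21516 one-gene rows matched the RefSeq table. XIST, TSIX and Y-linked genes were removed with 32 rows. Rows with several genes were not used to name any gene. KRT5, KRT6A, KRT16, KRT17, KRT77, HOXA13 and TYR were not named alone by any row, so they have no value. A gene's value was the median of its rows, which gave 17467 genes, 14864 of them from 1 row. The 25% of genes with the lowest mean log2 value, those under 3.53, were left out, and 13100 were tested. No coordinates are printed, since the gene table used and the build of the arrays differ. No exon usage was analysed here, because rows are gene-level.

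Sole was compared with back of foot in R 4.3.3 with limma 3.58.1, using lmFit and eBayes with a trend on mean expression and Benjamini-Hochberg adjustment at 0.05, two-sided. An exact permutation test of 2 against 2 arrays cannot give a p under 0.333, so no such test was used. Before the data were examined, 33 gene lists, the tests and the rule for naming genes were fixed. That rule takes 12 genes per direction by size among those past the threshold and separated between sites, filled up with separated genes that did not pass. It adds up to 4 members of each list named and a fixed set of keratin, patterning, pigment and Langerhans cell genes. Genes whose level follows common deletions or variable haplotypes were excluded from the first parts of the rule. Which of the lists that did not pass had their members named was decided after the results were seen. Lists were tested with camera at a preset inter-gene correlation of 0.01, with an estimated correlation and fry as alternatives. With an estimated correlation, camera takes its p from the residual degrees of freedom of 4 arrays, so that alternative has little power. Genes at least 2-fold apart with no overlap between sites were also counted, for the site split and for the other 2 splits of the 4 arrays.

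The procedure was tested on simulated data with 200 changed genes among 13100, in 20 sets. With variances drawn from the fitted prior, it recovered 12.3% of 2-fold changes, 89% of 4-fold changes and 98.9% of 8-fold changes, with 8.9 false calls per set. The changed genes included 50 at each of these sizes and 50 at 16-fold. So many true changes loosen the adjusted threshold, so these rates can overstate the recovery in the real comparison, where 1 gene passed. A first version, which gave each gene its own moderated variance, recovered 49.1% of 2-fold and 99.3% of 4-fold changes with 19.95 false calls per set, and the second source of variances was added after that was seen. A list of 20 genes shifted by 0.5 was called, at an unadjusted camera p under 0.05, in 20 of 20 sets under either source, and an unshifted list in 0. Genes were simulated independently of each other, whereas the cell cycle list has an estimated correlation of 0.79 and the Langerhans list 0.48. These counts therefore do not show how often lists of correlated genes are called falsely. The number of arrays limits the precision of every value. Alternatives covered normalization, the filter on dim genes, the rows of a gene, the variance model, a replicate block, the list test and leaving out each array.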

Results

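Basal keratinocytes, the cells of the deepest layer of the epidermis, were compared between volar skin of the sole and non-volar skin of the back of the foot. Each site was represented by 2 arrays, and 13100 genes were tested. Values are log2 expression values as deposited, given as mean ± SD over 2 arrays per site, and differences are sole minus back of foot.

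The comparison asks which genes distinguish volar from non-volar basal keratinocytes. CLEC2A, which encodes a C-type lectin of keratinocytes, fell in the sole, at 3.45 ± 0.31 against 6.35 ± 0.21 in the back of the foot (limma, SE 0.25, adjusted p = 0.0427). Its sole level lies under the dim cutoff of 3.53, the mean that 25% of the genes stay below, so the size of its difference is uncertain. Of 6 tested members of a list of volar and pressure keratins, 5 were lower in the sole, with KRT1 at 7.70 ± 0.48 against 10.11 ± 0.02. These were KRT1, KRT10, KRT2, KRT15 and KRT14, while KRT9, the keratin typical of palm and sole skin, was higher by 0.69. Over all genes 0 of these 6 keratins passed the adjusted threshold. KRT9 stood at 4.81 and 5.84 in the back of the foot and at 6.04 and 5.99 in the sole, so its difference rests largely on back of foot replicate 1. None of the pressure keratins KRT6A, KRT6B, KRT6C, KRT16 and KRT17 was tested. Cell cycle genes were higher as a list by a median of 0.56, and Langerhans cell markers were lower by a median of 0.44. These list calls were lost with an estimated inter-gene correlation, a test of little power with 4 arrays. Without back of foot replicate 1 the cell cycle list turned direction. Its genes were higher in replicate 2 than in replicate 1 at both sites, so that setting is unbalanced between replicate numbers. Between arrays of the same number, its median was higher in the sole by 0.67 for replicate 1 and 0.43 for replicate 2. However, no label says that numbers pair arrays, and its median was 4.90 in sole replicate 1 against 5.17 in back of foot replicate 2. Without back of foot replicate 2 the Langerhans call was lost (median -0.18).

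CLEC2A was the 1 gene past the threshold, and 0 genes passed in the other direction. At an unadjusted p under 0.05, limma gave 350 genes, 129 higher and 221 lower in the sole, where 655 would be reached by chance. The spread in this fit includes differences between replicate numbers, and with a replicate block the count was 812. The call of CLEC2A was lost without the array of back of foot replicate 1, and likewise without back of foot replicate 2. It was also lost with arrays centred on their median (limma adjusted p = 0.0816), with no filter on dim genes (0.0888) and with the highest-mean row per gene (0.0820). A replicate block ended it too (limma adjusted p = 0.0785). Without the variance trend the call was lost as well, and the smallest limma adjusted p of any gene was 0.0621. Between the sites, 65 genes lay at least 2-fold apart without overlap, 22 higher and 43 lower in the sole. The split by replicate number gave 256 such genes and the remaining split 44. Values of the 2 sites did not overlap at any size for 24.1% of the genes, where chance gives 33.3%.

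**Figure D1:**
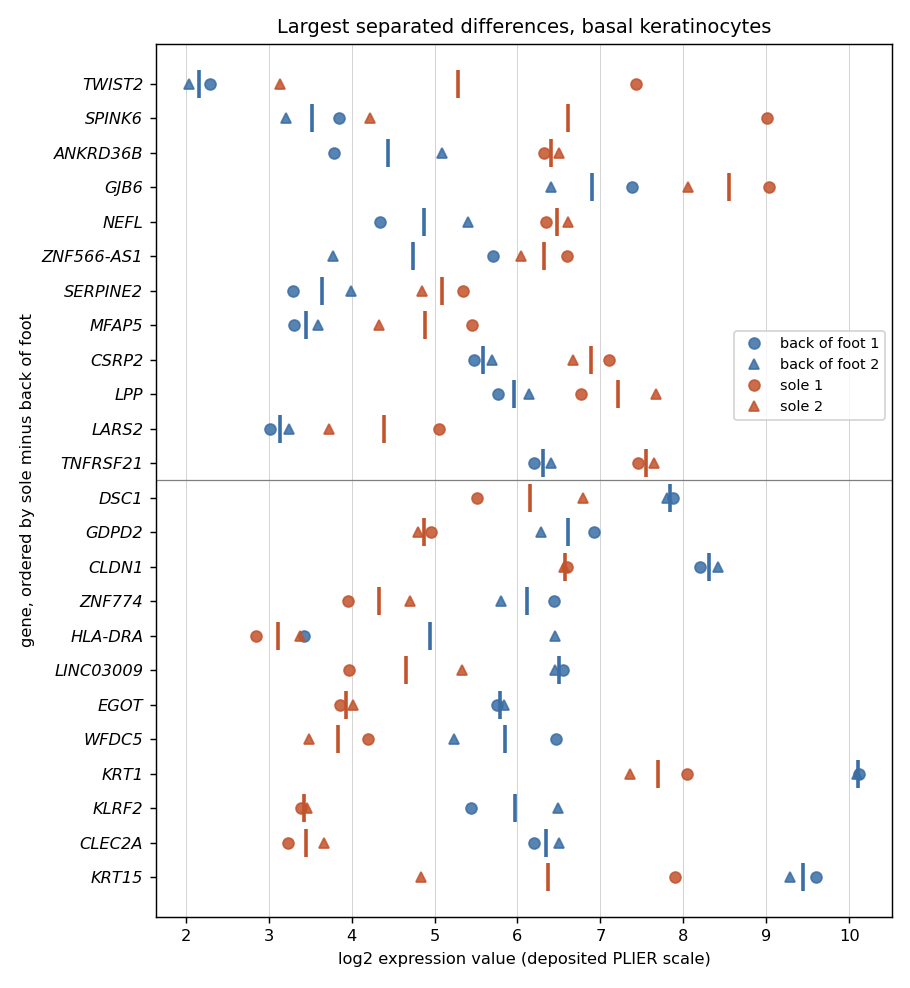
Log2 expression value of each array (x axis) for the 24 genes named by size of difference (y axis), 12 higher in the sole above the line and 12 lower below it; circles are replicate 1, triangles replicate 2, and vertical ticks the mean of 2 arrays. CLEC2A lies at 6.20 and 6.50 in the back of the foot and at 3.23 and 3.67 in the sole, and TWIST2 and SPINK6 are high in sole replicate 1 alone.

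Of the other genes lower in the sole, none passed the adjusted threshold. KLRF2, which encodes the natural killer cell receptor for the CLEC2A protein, differed by -2.54 (SE 0.34, limma adjusted p = 0.232) and lies within the span of CLEC2A in the RefSeq table. EGOT, a long non-coding RNA, differed by -1.86 with an SE of 0.22 (limma adjusted p = 0.187). The protease inhibitor gene WFDC5 differed by -2.01, LINC03009 by -1.85 (-1.16 without sole replicate 1), ZNF774 by -1.79 and GDPD2 by -1.73. HLA-DRA, an antigen presentation gene, differed by -1.83, with 3.42 and 6.46 in the back-of-foot arrays and 2.84 and 3.38 in the sole arrays. Without back of foot replicate 2 its difference was -0.31. The sole means of KLRF2 and HLA-DRA lie under the dim cutoff, so the sizes of their differences are uncertain.

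None of the genes higher in the sole passed. TWIST2, a transcription factor of mesenchymal cells, and SPINK6, a kallikrein inhibitor gene, differed by 3.11 and 3.09. TWIST2 stood at 7.43 in sole replicate 1 and 3.13 in sole replicate 2, and its difference without sole replicate 1 was 0.97. SPINK6 stood at 9.01 and 4.22, and its difference without sole replicate 1 was 0.70. More even between the sole arrays were NEFL, a neurofilament gene, at 1.60 (SE 0.36), the protease inhibitor gene SERPINE2 at 1.45 (SE 0.29) and TNFRSF21, a death receptor gene, at 1.24 (SE 0.27). CSRP2 and LPP, which encode LIM domain proteins, differed by 1.30 and 1.26, and LPP by 0.80 without sole replicate 2. MFAP5, a microfibril gene, differed by 1.44 and LARS2 by 1.26, but by 0.88 and 0.60 without sole replicate 1. ZNF566-AS1 differed by 1.57, and by 0.61 without back of foot replicate 2. The back-of-foot means of TWIST2 (2.16), SPINK6 (3.52), MFAP5 (3.45) and LARS2 (3.14) lie under the dim cutoff of 3.53, so the sizes of these 4 differences are uncertain. ANKRD36B differed by 1.97, but it belongs to a family of near-identical copies, and its value is uncertain.

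Volar and pressure keratins formed the list with the largest median difference, -1.20 over 6 tested of 13 fixed members. Of these 5 were lower in the sole (camera adjusted p = 1.92e-06), and none of KRT6A, KRT6B, KRT6C, KRT16 and KRT17 was tested. Without sole replicate 2 the list's median was -0.72. With an estimated correlation its p = 0.0549, or adjusted p = 0.906. Over all genes 0 members passed, and adjusted over the list alone 4 passed: KRT1, KRT10 and KRT2, keratins of the differentiating layers, and KRT15, a basal keratin. KRT1 differed by -2.41 with an SE of 0.32 (limma adjusted p = 0.232 over all genes). KRT10 differed by -1.53 and KRT2 by -0.88, and without sole replicate 2 by -0.85 and -0.44. KRT15 differed by -3.08, with 9.60 and 9.29 in the back of the foot and 7.90 and 4.83 in the sole, and by -1.55 without sole replicate 2. KRT9, the keratin typical of palm and sole skin, stood at 6.02 ± 0.03 in the sole and 5.33 ± 0.73 in the back of the foot. Its back-of-foot values were 4.81 in replicate 1 and 5.84 in replicate 2. The difference of 0.69 did not pass, was 0.17 without back of foot replicate 1, and was larger without back of foot replicate 2. KRT14, the main basal keratin with a named row, differed by -0.36 (-0.14 without sole replicate 1), and ITGA6, which encodes the integrin used for the sort, by 0.18 (0.085 without back of foot replicate 1).

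Spinous and granular differentiation genes were lower as a list, with 15 of 22 below and a median of -0.17 (camera adjusted p = 0.000170). The median was -0.094 with no filter on dim genes and -0.26 with the lowest 50% left out. With an estimated correlation p = 0.290 and adjusted p = 0.911. This list shares KRT1, KRT10 and KRT2 with the volar and pressure keratins. Adjusted over the list alone, KRT1 and DSC1 passed, and over all genes 0 did. DSC1, a desmosomal cadherin of the upper epidermis, differed by -1.69, and by -1.05 without sole replicate 1. CASP14, the caspase of cornification, differed by -2.52, and by -0.36 without sole replicate 2, with 3.85 in sole replicate 2 against 8.16 in sole replicate 1. The call was lost without back of foot replicate 1 (camera adjusted p = 0.284, median 0.037) and without sole replicate 2 (camera adjusted p = 0.278, median 0.0061), and the median was -0.30 without back of foot replicate 2 and -0.45 without sole replicate 1.

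Adhesion junction genes did not pass as a list (camera adjusted p = 0.565), with 12 members above and 9 below. Adjusted over the list alone 3 members passed, in opposite directions, and over all genes 0. CLDN1, a tight junction claudin, differed by -1.73 with an SE of 0.27, at 6.58 ± 0.03 in the sole and 8.31 ± 0.16 in the back of the foot. The gap junction connexin genes GJB6 and GJB2 were higher in the sole by 1.65 and 1.06. DSC2 differed by 0.50, by 0.25 without back of foot replicate 1 and by 0.30 without sole replicate 1.

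Cell cycle genes were higher in the sole for 22 of 22 tested members, with a median difference of 0.56 (camera adjusted p = 1.92e-06). An estimated correlation gave p = 0.304 and adjusted p = 0.911. The mitotic cyclin gene CCNB2 differed by 1.05 (SE 0.73), MKI67, a proliferation marker, by 0.95 (SE 0.58), BIRC5 by 0.94 and CCNB1 by 0.83. Without back of foot replicate 1, MKI67 differed by 0.17, CCNB2 by -0.12, BIRC5 by -0.014 and CCNB1 by -0.28. Without sole replicate 2 MKI67 differed by 0.24. No member passed over all genes or adjusted over the list alone. The same genes differed between replicate numbers by a larger amount, with replicate 2 above replicate 1 by a median of 1.17 in the back of the foot and 1.03 in the sole. Between arrays of the same number, sole was above back of foot by a median of 0.67 for replicate 1 and 0.43 for replicate 2. No label pairs the numbers, and the list's median in sole replicate 1, 4.90, lay below that in back of foot replicate 2, 5.17. The call was lost without sole replicate 2 (camera adjusted p = 0.748, median 0.11), and without back of foot replicate 1 the direction turned (camera adjusted p = 0.629, median -0.032), while the median was 1.15 without back of foot replicate 2 and 1.20 without sole replicate 1.

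**Figure D2:**
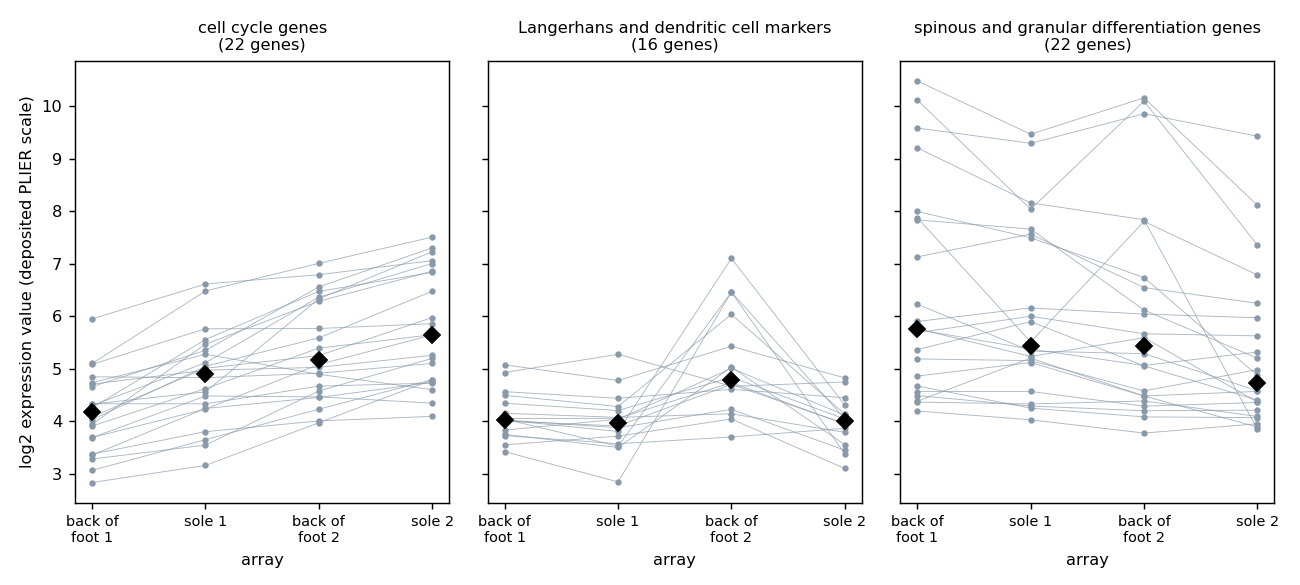
Log2 expression value (y axis) of each gene in 3 gene lists on each of the 4 arrays (x axis); thin lines join the values of a gene, and black diamonds are the median of the list on that array. Medians of the cell cycle list are 4.17 and 5.17 in the back of the foot and 4.90 and 5.64 in the sole, and the Langerhans list is highest in back of foot replicate 2, at 4.79.

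Langerhans and dendritic cell markers were lower in the sole for 14 of 16 tested members, with a median of -0.44 (camera adjusted p = 3.90e-07), which was -0.75 with the lowest 50% left out and -0.72 without back of foot replicate 1. Estimating the inter-gene correlation gave p = 0.167 and adjusted p = 0.911. CD207, the Langerhans cell lectin, had values of 4.02 and 7.10 in the back of the foot and 3.81 and 4.31 in the sole. HLA-DPA1 differed by -1.46 and CD74, the invariant chain of antigen presentation, by -1.06. No member passed over all genes or adjusted over the list alone. Without back of foot replicate 2 the call was lost (camera adjusted p = 0.260), and CD207 differed by 0.034, HLA-DPA1 by -0.25 and CD74 by -0.29. That array stood apart for melanocyte markers too: the Langerhans list was higher in back of foot replicate 2 than in replicate 1 for 13 of 16 members (median 0.59) and the melanocyte list for 13 of 14 (median 0.73). The melanocyte list was called higher in the sole without back of foot replicate 2 (camera adjusted p = 0.00338, median 0.39) and lower without back of foot replicate 1 (camera adjusted p = 5.38e-05, median -0.36).

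Inflammatory cytokine and chemokine genes were lower for 13 of 17 members, with a median of -0.44 (camera adjusted p = 1.20e-05), which was -0.20 with no filter on dim genes and -0.71 without sole replicate 1. An estimated correlation gave p = 0.0352 and adjusted p = 0.906. TNFAIP3, an inhibitor of NF-kB signalling, differed by -1.03 (-0.60 without sole replicate 2), IL1RN by -0.86, the prostaglandin synthase gene PTGS2 by -0.86 and IL1A by -0.72. Immediate early and dissociation genes, which respond within minutes to handling of cells, were lower for 17 of 19 members, with a median of -0.32 (camera adjusted p = 7.91e-05). With an estimated correlation p = 0.289 and adjusted p = 0.911. ATF3 differed by -0.92, ZFP36 by -0.85, CCN1 by -0.75 and FOSB by -0.68. Without sole replicate 2, ZFP36 differed by -0.43 and FOSB by -0.0014, and without back of foot replicate 1, CCN1 differed by -0.28. The call of this list was lost without back of foot replicate 1 (camera adjusted p = 0.338, median -0.16) and without sole replicate 2 (camera adjusted p = 0.364, median -0.0059), and the median was -0.62 without back of foot replicate 2 and -0.59 without sole replicate 1. In both lists 0 members passed, over all genes or adjusted over the list alone.

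Limb patterning transcription factors were higher for 13 of 18 members, with a median of 0.13 (camera adjusted p = 0.00327), which was 0.20 with the lowest 50% left out. An estimated correlation gave p = 0.122 and adjusted p = 0.911. The homeobox genes DLX5 and DLX6 differed by 0.996 (SE 0.26) and 0.72 (SE 0.24), TFAP2B by 0.68 and IRX5 by 0.37 (0.040 without sole replicate 1), and 0 members passed over all genes or adjusted over the list alone. The call was lost without back of foot replicate 1 (camera adjusted p = 0.157) and without sole replicate 1 (camera adjusted p = 0.151). HOX genes of the posterior and distal groups did not pass (camera adjusted p = 0.902), with a median of -0.045 and a mean and test in the other direction. HOXC9 differed by 0.52, HOXD12 by 0.39, HOXD10 by -0.33, HOXC10 by 0.32, HOXD13 by 0.28 and HOXC13 by -0.17. Without sole replicate 1, HOXD12 differed by -0.12, HOXC10 by -0.11, HOXD13 by 0.12 and HOXC13 by 0.064.

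WNT pathway genes did not pass either (camera adjusted p = 0.904; median -0.037). WNT5A differed by 0.74 (0.33 without sole replicate 2), WNT3 by -0.65, FZD7 by 0.55 and WNT7A by -0.52 (-0.32 without sole replicate 1). EN1, a homeobox gene of ventral limb skin, differed by 0.33 with an SE of 0.24. The WNT inhibitor gene DKK3 differed by -0.11 (0.035 without back of foot replicate 1), and DKK1, at 2.87 ± 0.05 in the back of the foot and 2.88 ± 0.15 in the sole, was too dim to be tested. TYRP1, a melanocyte gene, differed by -0.013, and by 0.62 without back of foot replicate 2.

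**Figure D3:**
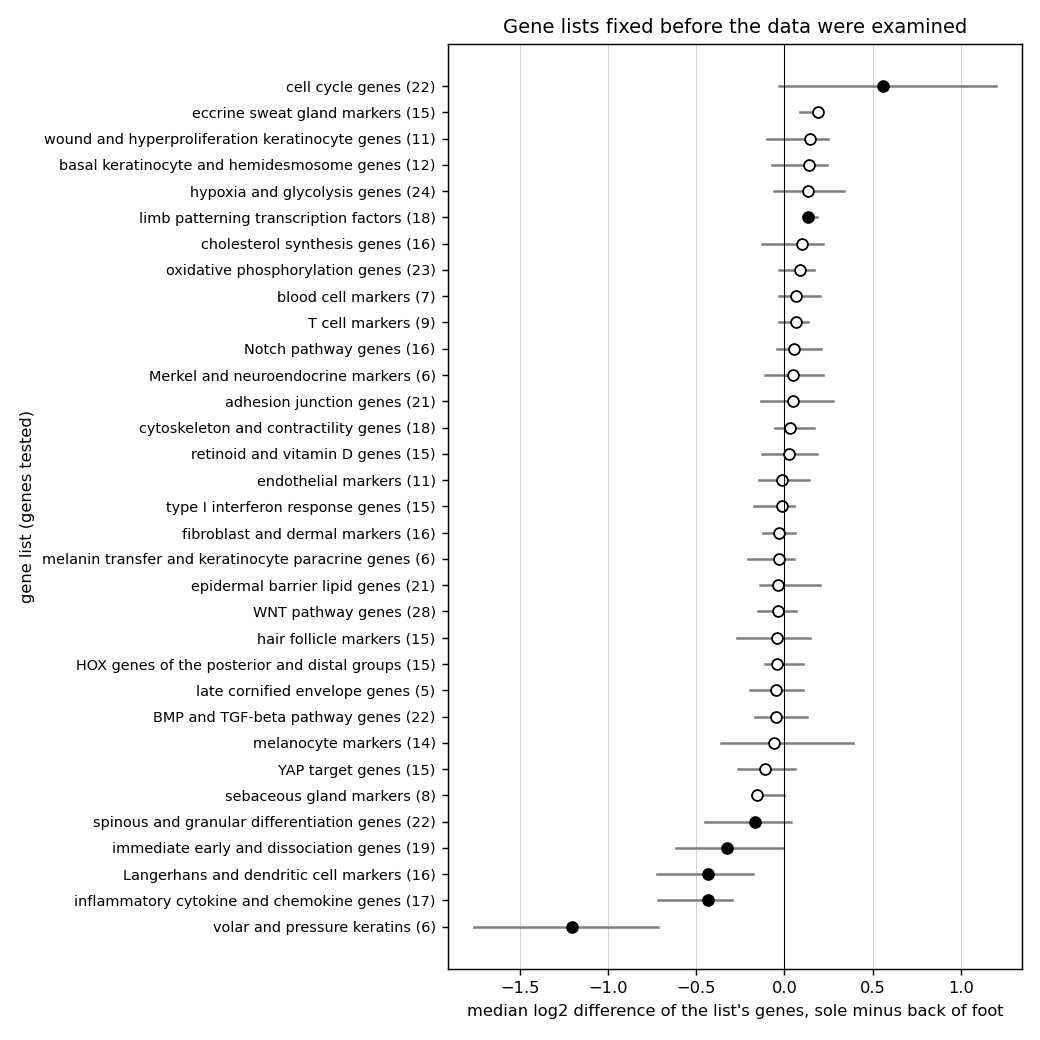
Median log2 difference of each of the 33 gene lists (x axis, sole minus back of foot), with the number of genes tested after each name (y axis); filled points are the 7 lists past a camera adjusted p of 0.05 at the preset correlation, and grey lines span the medians found on leaving out each array. The list of volar and pressure keratins has the lowest median, -1.20, and the cell cycle list the highest, 0.56.

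Of the 33 lists, 7 passed with the preset correlation, 5 lower and 2 higher, and 26 did not, with camera adjusted p from 0.0862 to 0.991 and medians from -0.15 to 0.19. Markers of melanocytes (median -0.061), T cells (0.064), fibroblasts (-0.030, with a mean of 0.13), endothelium (-0.015, with a test in the other direction) and blood cells (0.066) were among the latter. On each array the medians of the T cell, endothelium and blood cell lists lay below that of all tested genes. Small differences of such dim lists say little about these cells. With an estimated correlation 0 lists passed after adjustment and 1 had an unadjusted p under 0.05, and fry called 0. That 1 list, the inflammatory genes, had an estimated correlation of -0.013, below the preset 0.01. Its camera p still went from 1.45e-06 to 0.0352, because the few residual degrees of freedom of 4 arrays then set the p. The loss of the calls therefore cannot be put down to inter-gene correlation alone.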

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

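Of the alternatives here, the replicate block with an estimated correlation or with fry, and every row of the table in place of named genes, were chosen after seeing the data. CLEC2A passed with quantile normalization, the lowest 50% left out, the mean of rows and a robust fit, with 1 gene each. The count was 0, in total and lower in the sole, with arrays centred on their median, no filter on dim genes, the highest-mean row, no variance trend and every row of the table, where 6351 rows (4.30%) had an unadjusted p under 0.05. Where named genes were recomputed, the adjusted p of CLEC2A ranged from 2.23e-14 to 0.308. Leaving out each array gave 0 to 128 genes, 0 to 61 higher and 0 to 67 lower; a lone array is then assumed to vary like the others, and the cause was not tested. Genes 2-fold apart numbered 45 to 96 in other settings, 349 at 1.5-fold, where the criterion is looser, and 150 to 244 without an array, where fewer values can overlap.

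Same-numbered arrays deviated together from their site means, with a correlation of 0.42 across genes. With 2 arrays per site both pairs give this same value, so it is a single comparison. Pearson correlations between arrays were 0.934 and 0.942 for the same number, against 0.911 and 0.895 for the same site. However, no label says that numbers pair arrays. With the replicate block 0 genes passed, in total and lower in the sole, and CLEC2A had a limma adjusted p of 0.0785. An unadjusted p under 0.05 was reached by 812 genes, where chance gives 655, and 7 lists were called. Lists called numbered 7 to 9 in other settings and 4 to 10 without an array, but 0 with an estimated correlation, 0 with fry, and 0 with the block and either. The adjusted p of the cell cycle list ranged from 4.09e-33 to 0.748 without an array, with the direction turned without back of foot replicate 1.

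Among named genes, 460 of 466 differences outside the left-out arrays kept direction and side of the threshold. TYRP1 turned to 0.010 with quantile normalization and WNT7A to 0.17 with the highest-mean row; the cause was not tested. Leaving out 1 array moved 39 of 68 differences by over 1.5 times or past 0. Without an array, ranges crossed 0 for DKK3 (-0.26 to 0.035), HOXC13 (-0.50 to 0.17), CCNB2 (-0.12 to 2.22), BIRC5 (-0.014 to 1.89), CCNB1 (-0.28 to 1.94), TYRP1 (-0.64 to 0.62), CD207 (-3.05 to 0.034), HOXD12 (-0.12 to 0.89) and HOXC10 (-0.11 to 0.75). A log2 offset was not applicable to log2 values, and the exon usage alternatives were not run on gene-level rows. Signal over background limits dim genes such as DKK1.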

Other observations

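The tests of explanations below were chosen, and their bounds set or revised, only after the results were seen; the list results were planned.

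Hair follicle markers did not pass as a list (camera adjusted p = 0.763), with 7 of 15 members above and 8 below. Adjusted over the list alone 2 passed, and over all genes 0. GATA3, a transcription factor of epidermis and inner root sheath, differed by -1.38 with an SE of 0.23, at 4.45 ± 0.20 in the sole and 5.83 ± 0.12 in the back of the foot. TNC, the matrix glycoprotein tenascin C, differed by 0.79 with an SE of 0.21. SOX9 differed by 0.59 (0.10 without sole replicate 1) and TCHH, which encodes trichohyalin, by -0.49 (-0.26 without back of foot replicate 1). Of the melanin transfer and keratinocyte paracrine genes (camera adjusted p = 0.180), ADAM17, a sheddase gene, passed over the list alone with a difference of -1.10 (-0.73 without sole replicate 1), and it was not followed through the other alternatives.

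CLEC2A and KLRF2 were lower together in the sole. Natural killer cells in the back-of-foot sorts would bring their other transcripts, yet 11 markers above the dim cutoff had a median difference of 0.0320 (bootstrap 95% interval -0.076 to 0.069). That interval resamples markers measured on the same 4 arrays, so it holds no spread between arrays. Among the 11, GNLY, PRF1, CD247, CST7 and EOMES lay below the median tested gene at both sites, so their small differences exclude little. IL2RB, at 4.21 in the sole against 4.82 in the back of the foot, goes with the explanation, 6 further markers are too dim to exclude it, among them FGFBP2 at -0.34, and it stays open although the sort is meant to leave such cells out. CLEC2A transcript read by the probes of KLRF2, a gene within its span, may account for the pair. The gap between the 2 differences was 0.356, but the sole means of both genes, 3.45 and 3.42, lie under the dim cutoff of 3.53. This gap therefore decides nothing. In the back of the foot, where both lie above the cutoff, replicate 2 exceeded replicate 1 by 0.30 for CLEC2A and 1.05 for KLRF2. Cross-reading predicted changes within the summed standard errors of 0.586, and they lay 0.745 apart. Those standard errors belong to site differences between means of 2 arrays, whereas a change between replicates compares single arrays and varies more. The bound is therefore too narrow, and the gap of 0.745 decides nothing. With 2 arrays per site the explanation still cannot be told apart from separate regulation. A site difference in CLEC2A itself stays open and untested.

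Langerhans cell markers were lower in the sole sorts. Langerhans cells mostly in back of foot replicate 2 could produce the list's call, although the sort is meant to leave such cells out. Without that array the median moved from -0.435 to -0.181. The list was highest in that array, at 4.79 against 4.03 in back of foot replicate 1, so a smaller difference was fixed in advance. The move therefore restates the pattern and does not test the explanation. Melanocyte markers were also higher in that array than in replicate 1, by a median of 0.727. Fewer of these cells in the sole at both replicates also stays open: the medians between same-numbered arrays were both below 0, at -0.144 and -0.792, and only the latter lay beyond 0.2, so 2 arrays per site are too few to decide.

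KRT1, KRT10 and DSC1 were lower in the sole. A smaller share of differentiating cells of every layer in the sole sorts may account for this, and then the other spinous and granular genes would fall too. Of those, 12 brighter than the median tested gene had a median of -0.211, with a bootstrap 95% interval of -0.838 to 0.080 and 5 at or below -0.5, so the explanation stays open. Among these 5, CASP14 and KRT2 stood lower in sole replicate 2 (3.85 and 4.37) than in sole replicate 1 (8.16 and 5.23). The call of the whole list was lost without sole replicate 2 and also without back of foot replicate 1. Over all 19 other members the median was -0.094 (-0.360 to 0.036), an interval above -0.5, but 5 of the 19 lie at or below -0.5 and go with the explanation; the brighter members were made the deciding set after the value over all 19 was seen. Both intervals resample genes measured on the same 4 arrays, so they hold no spread between arrays. A site difference in KRT1, KRT10 and DSC1 within basal cells also stays open.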
